A study of Homo sapiens with 12 samples.

How the data were processed

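RNA of BeWo cells was measured on 12 one-colour Agilent arrays, 2 for each of the 6 combinations of TNF (none, 100 pg/ml or 100 ng/ml) and IGF-I (none or 100 ng/ml), after 48 h. Each array held 62976 spots, of which 60901 were not controls. The deposited scanner files hold spot intensity values, background-subtracted and corrected by Feature Extraction 10.7.3.1, per the file headers. The deposited value table is in log2 units: it equals the log2 of the same processed signal plus 1 constant per array, and it was used as an alternative only.

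From the scanner files, spots marked as non-uniform or as population outliers were left out, and the log2 of the processed signal was averaged per probe. The array's 75th percentile was then subtracted. Of 58201 probes, 46 that were outliers on an array were left out. A probe was kept when it was well above background on both arrays of at least 1 group, by the scanner's own mark, which left 27223 probes. Probes were named through the RefSeq accession they carry: 31104 had 1 symbol and 27097 had none, and the latter were kept under their own identifier. For each gene the probe with the highest mean signal was used, which gave 22157 genes, 14952 of them with a symbol. The headers give another genome build than the naming table, so no coordinates are given.

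Groups were compared with limma 3.58.1 in R 4.3.3, in a model with 1 mean per group, 6 residual degrees of freedom and a prior of 2.90, with p-values adjusted by the method of Benjamini and Hochberg at a false discovery rate of 0.05. The comparisons were each TNF dose against none, averaged over IGF-I and within each IGF-I level, the doses against each other, IGF-I averaged over TNF and without TNF, and the interactions of each dose with IGF-I. The 28 gene lists were fixed in advance, and the 27 with at least 4 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. A fold change against a group in which no array was well above background is given as a lower bound. The bound holds for the processed signal of the main fit only, and some alternatives gave smaller changes.

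Genes were named by a rule: the 12 called genes with a symbol and the largest change in each direction whose arrays all lay beyond those of the other group, for the smaller comparisons those with the smallest p, up to 4 members of each list with the smallest p and any called member, and a fixed set of TNF-response, trophoblast hormone and insulin-signalling genes. ISG15, STAT1, HLA-G, CD14 and ATF4 for TNF high, and TRIB3 and ASNS for IGF-I, fall outside the rule and were chosen after their values were seen. Of the genes called for TNF high with all arrays beyond, 2509 had a symbol and 722 did not. The groups, comparisons, lists, naming rule and first alternatives were chosen before the data were examined.

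The fit was tested on simulated data with 200 changed genes among 22157. For TNF high averaged over IGF-I it recovered 0% of genes changed by 0.5 on the log2 scale, 88% at 1 and 99% at 2, for IGF-I averaged over TNF 42.5%, 96% and 99%, and for TNF high without IGF-I 0%, 69% and 97.5%. The cutoff of a false discovery rate is stricter when fewer genes change. In the data 3326 genes were called for TNF high on average, among them CGA at 0.46, so the 0% at 0.5 does not carry over. A list that was shifted in the simulation was the 1 list called. The simulation drew genes independently, so it could not test camera's preset correlation between genes. It used each gene's spread as limma had already drawn it towards a common value, the same on every array. The shares recovered may thus be too high.

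The arrays lay on 2 slides. All first replicates and the second replicates of control and TNF low were on slide 1, and the other 4 arrays were on slide 2. The labels pair no samples, and the replicate numbers were checked as pairs: in 4 of the 15 pairs of groups the deviations of the replicates correlated above 0.1 (range -0.168 to 0.252), so samples were not paired. Alternatives were normexp background correction, quantile normalization, no filter on dim probes, a filter on all 12 arrays, slide or replicate number as a block, only the groups compared, a trended robust variance, all probes, the authors' value table and leaving out each array. The files hold no mean signal per spot, so normexp used the median signal. Leaving out both arrays with a larger spot-to-spot spread, and slide 1 alone, were added after the data were seen. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.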

Results

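Gene expression was measured in BeWo cells, a human choriocarcinoma line widely used as a model of the trophoblast of the placenta. The cells were kept for 48 h without or with tumour necrosis factor alpha (TNF), an inflammatory cytokine, and without or with insulin-like growth factor I (IGF-I), a growth factor. TNF was given at 100 pg/ml (TNF low) or 100 ng/ml (TNF high), and IGF-I at 100 ng/ml. The 3 TNF levels and 2 IGF-I levels made 6 groups of 2 arrays each, 12 one-colour Agilent arrays in all. Between 44.2% and 50.1% of the spots of an array were well above background and no spot was saturated. Replicate arrays correlated across genes with r between 0.989 and 0.996. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Signals are normalized log2 values, in which 0 is the 75th percentile of an array, and 22157 genes were tested with limma. The first principal component carried 33.3% of the variance. It placed the 4 TNF-high arrays between 27.9 and 39.7 and the other 8 between -23.1 and -10.4. TNF-low replicate 1 stood apart on the second component (17.7% of the variance, 57.1 against -14.4 to 8.16) and control replicate 1 on the third (11.6%, 45.9 against -13.7 to 4.16). These 2 arrays also had a larger spread between spots of the same probe (median coefficients of variation of 6.88% and 9.03%) than the other arrays (3.59% to 4.29%).

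The first comparison asked what TNF at 100 ng/ml did to the cells, averaged over both IGF-I levels (4 arrays against 4). The largest rise was that of LFNG (RefSeq NM_001040167), a glycosyltransferase that modifies Notch receptors, at 26.0-fold (log2 fold change 4.70 ± 0.10 SE). Others that rose were the cytokine gene IL32 (12.6-fold), complement component C3 (10.8-fold), the TNF gene itself (log2 fold change 3.42 ± 0.14), the protease gene CTSE (9.07-fold), the retinoic-acid-degrading enzyme CYP26A1 (6.65-fold), the NF-kB subunit RELB (6.34-fold) and the germ-cell transcription factor SOHLH1 (6.32-fold). Over the alternatives the log2 fold change of SOHLH1 ranged from 1.34 to 2.81. LTB (lymphotoxin beta), SAA4 (serum amyloid A), NOG (a BMP antagonist) and UBD (a ubiquitin-like protein) were not well above background on any untreated array. On the processed signal they rose at least 7.31-fold, 2.79-fold, 2.73-fold and 1.60-fold, respectively. With normexp background, which adds an offset of 50 to each signal, their log2 fold changes were 1.22, 0.59, 0.55 and 0.45, below these bounds.

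Genes that fell with TNF high included SLC7A11, the cystine transporter (log2 fold change -2.91 ± 0.16 SE), and the long noncoding RNA VLDLR-AS1 (-2.39 ± 0.16), both well above background on all 4 TNF-high arrays. LYPD4 (-3.89 ± 0.24) and DRD5, a dopamine receptor gene (-3.38 ± 0.25), fell and were well above background on 3 of the 4. GDAP1L1 (-4.54 ± 0.43), SLC7A11-AS1 (-2.60 ± 0.24) and SH3BP2 (-2.52 ± 0.59) fell and were well above background on 1 of the 4, so these values are uncertain. The complement genes C5 and C5AR1, the stress hormone gene FGF21 and the inhibin subunit INHBE were not well above background on any TNF-high array and fell at least 2.30-fold, 2.39-fold, 3.22-fold and 2.70-fold on the processed signal. With normexp background their log2 fold changes were -0.66, -0.64, -0.68 and -0.57, smaller than these bounds. SLC4A5 also fell (at least 1.46-fold). The adjusted p was 0.022 for SH3BP2 and 0.017 for SLC4A5 in limma. SH3BP2 lost its call when any of 4 single arrays was left out, and SLC4A5 when any of 3 was. SLC4A5 was well above background on 1 untreated and 0 TNF-high arrays.

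In all, limma called 3326 of the 22157 genes at a false discovery rate of 0.05, 1730 higher and 1596 lower with TNF high. Of these, 159 rose and 217 fell by at least 2-fold. All TNF-high arrays lay beyond the untreated arrays within both IGF-I levels for 1687 of the higher and 1544 of the lower genes. These genes were called from the same arrays, so this was largely fixed by the call. Over all 22157 tested genes, called or not, 3828 lay higher and 3061 lower in this way. Chance alone gives this, in 1 direction or the other, for 5.56% of tested genes. With slide as a block 2812 genes were called, and on slide 1 alone (8 arrays, 2 TNF-high arrays against 3) 134. Leaving out 1 array moved the count by over 1.5 times for 5 arrays, to 2020 and 1758 without TNF-high replicates 1 and 2, 1694 and 1863 without IGF-I replicates 1 and 2, and 2000 without IGF-I plus TNF-high replicate 1. Without a filter on dim probes the count was 944. Which direction had more genes also depended on the setting, with 1189 higher and 1379 lower without control replicate 1 and 423 and 521 without the filter.

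**Figure D1:**
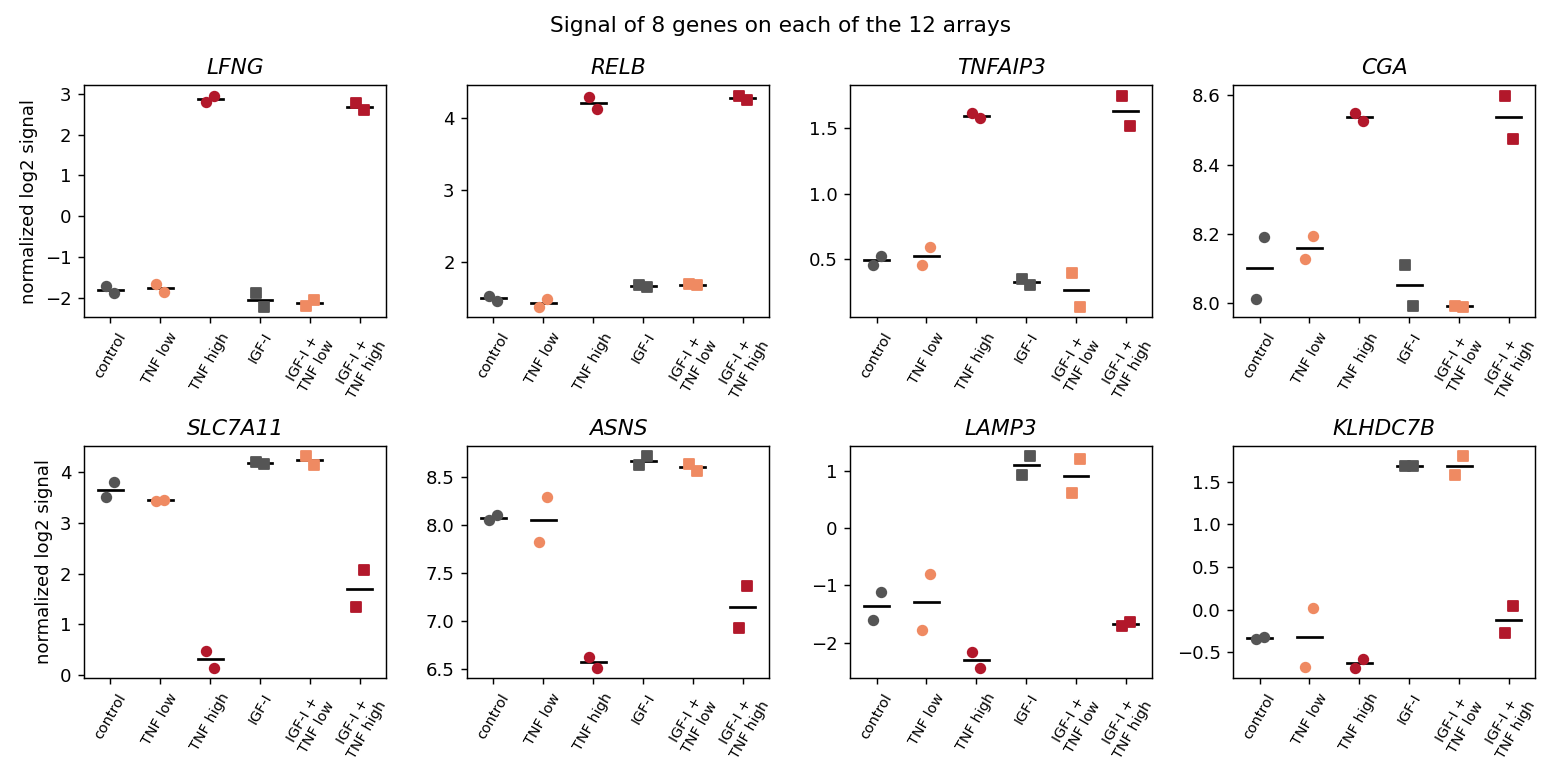
Normalized log2 signal (vertical axis) of 8 genes on each of the 12 arrays, by group along the horizontal axis; points are single arrays (circles without IGF-I, squares with it), horizontal lines are group means of 2 arrays. LFNG, RELB, TNFAIP3 and CGA were higher on all 4 TNF-high arrays, SLC7A11 and ASNS were lower on them, and LAMP3 and KLHDC7B were higher with IGF-I at each TNF level.

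Genes of the NF-kB and TNF response made up the most shifted list. Of its 36 tested members 25 rose with TNF high and 1, the iron-binding lipocalin LCN2, fell (-0.65 ± 0.15 SE). Adjusted over the list alone, 30 rose and 1 fell. The fall of LCN2 ranged from -0.82 to -0.20 over the alternatives, and 10 of 22 ended its call. Besides C3, IL32, RELB, TNF and LTB, the acute-phase genes SAA2 (2.49 ± 0.10) and SAA1 (2.22 ± 0.09) rose. So did the adhesion molecule ICAM1 (1.43 ± 0.08), the apoptosis inhibitor BIRC3 (1.40 ± 0.22) and the feedback inhibitors TNFAIP3 (1.21 ± 0.09) and NFKBIA (0.99 ± 0.10). SOD2, the mitochondrial superoxide dismutase, had a log2 fold change of 0.27 ± 0.09 that did not pass (adjusted p = 0.094). The probes of the near-identical SAA1 and SAA2 may share signal. The list as a set stood above the other genes in limma's camera test (adjusted p = 2.87e-22). With an estimated correlation between its genes the adjusted p was 0.146.

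Immune genes of other lists rose with it. Of 11 tested cytokine and chemokine genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), among them CCL28 (1.35 ± 0.11 SE), CXCL16 (1.16 ± 0.12), IL15 (1.07 ± 0.11) and IL23A (0.76 ± 0.08). CXCL8 and CCL2 were not well above background on both arrays of any group and were not tested. Of 32 interferon-response genes 16 rose and 0 fell (21 and 0 over the list alone), led by the RNA sensor IFIH1 (1.57 ± 0.09), GBP4 (1.56 ± 0.09), OAS3 (1.36 ± 0.10) and IFIT3 (2.13 ± 0.19), while ISG15 (0.20 ± 0.10) and STAT1 (0.20 ± 0.11) did not pass. Over the alternatives OAS3 ranged from 0.66 to 1.45 and IFIT3 from 0.33 to 2.31. Of 22 genes of MHC class I and antigen processing 14 rose and 0 fell (16 and 0 over the list alone). They included the immunoproteasome subunit PSMB9 (2.13 ± 0.08), the tapasin gene TAPBP (1.32 ± 0.08), TAPBPL (1.26 ± 0.10) and the peptide transporter TAP1 (0.98 ± 0.10). The class I heavy chain gene HLA-B rose (0.31 ± 0.08) and HLA-G did not pass (0.25 ± 0.09), and probes of these related genes may share signal. HLA-B lost its call in 14 of 23 alternatives. In camera the adjusted p was 0.00022 for the cytokines, 6.32e-11 for the interferon response and 1.39e-10 for MHC class I. Each list's adjusted p was 0.146 with an estimated correlation.

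Genes of cell death, p53 targets and genes of the cell cycle itself rose more often than they fell. Of 36 death receptor and apoptosis genes 10 rose, including the BH3-only gene BIK (1.32 ± 0.11 SE), the decoy receptor TNFRSF10C (0.88 ± 0.10) and the TNF receptor TNFRSF1B (0.77 ± 0.11), and 1, the survival gene BCL2L1, fell (-0.28 ± 0.07). Adjusted over the list alone, 12 rose and 2 fell. BCL2L1 lost its call in 15 of 23 alternatives. Of 23 p53 targets 10 rose and 1 fell (11 and 2 over the list alone), with POLH at 1.05 ± 0.09, MDM2 at 0.87 ± 0.16 and the cyclin-dependent kinase inhibitor CDKN1A at 0.68 ± 0.10. Of 39 cell cycle genes 12 rose and 0 fell (16 and 0 over the list alone), among them RRM2 (0.74 ± 0.10), UHRF1 (0.69 ± 0.12), TYMS (0.64 ± 0.09) and CDK1 (0.61 ± 0.11). Camera's adjusted p was 0.00027, 8.24e-05 and 1.48e-06 for these 3 lists. With an estimated correlation the adjusted p was 0.439, 0.236 and 0.280.

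Trophoblast genes moved in both directions. Of 20 genes of syncytiotrophoblast hormones and steroid synthesis 6 rose and 0 fell (9 and 0 adjusted over the list alone). These were HSD11B2, which inactivates cortisol (1.81 ± 0.08 SE), leptin LEP (0.64 ± 0.10), aromatase CYP19A1 (0.62 ± 0.10), ADM (0.56 ± 0.09) and the chorionic gonadotropin subunits CGB3 (0.49 ± 0.10) and CGA (0.46 ± 0.08). CGB3 belongs to a family of near-identical genes that its probe may not tell apart. Of 21 fusion and syncytial differentiation genes 5 rose and 3 fell (the same counts over the list alone). The transcription factors GCM1 (0.66 ± 0.10) and OVOL1 (0.55 ± 0.08) rose, the amino acid transporters SLC1A4 (-1.42 ± 0.16) and SLC1A5 (-0.99 ± 0.12) fell, and the fusogens ERVW-1 (-0.01 ± 0.10) and ERVFRD-1, well above background on 1 of 4 untreated and 3 of 4 TNF-high arrays, did not pass. Of 29 cytotrophoblast and stem cell genes 8 fell and 0 rose (10 and 1 over the list alone), including the transcription factors CDX2 (-1.16 ± 0.23) and TP63 (-0.89 ± 0.17), PAGE4 (-0.71 ± 0.15) and ELF5 (-0.47 ± 0.11). CDX2 ranged from -1.35 to -0.308, TP63 from -0.997 to -0.319 and PAGE4 from -0.862 to -0.205 over the alternatives. The call ended in 2 of 22 for CDX2, 2 of 22 for TP63 and 6 of 22 for PAGE4. Of 26 genes of extravillous trophoblast and invasion 10 rose and 0 fell (16 and 0 over the list alone). They included the plasminogen activator inhibitor SERPINE1 (2.10 ± 0.12), the neurokinin gene TAC3 (2.08 ± 0.14), the gelatinase MMP9 (1.18 ± 0.08) and the integrin ITGA5 (0.48 ± 0.09). As sets, these lists had a camera adjusted p of 0.0060 for hormones, 0.175 for fusion, 0.0027 for cytotrophoblast and 3.25e-09 for invasion genes. With an estimated correlation the adjusted p was 0.297, 0.439, 0.280 and 0.146. Only 1 pregnancy-specific glycoprotein gene was tested, and PSG1 was not well above background on both arrays of any group.

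In the list of the amino acid and ER stress response more genes fell than rose. Of its 31 tested members 18 fell and 2 rose (20 and 4 adjusted over the list alone). The glutathione-degrading enzyme CHAC1 (-1.80 ± 0.14 SE), the pseudokinase TRIB3 (-1.62 ± 0.15), asparagine synthetase ASNS (-1.52 ± 0.13), the serine synthesis enzymes PSAT1 (-1.33 ± 0.12) and PSPH (-1.33 ± 0.09), and DDIT3 (-1.22 ± 0.11) fell. ATF4, the transcription factor of this response, did not pass (-0.29 ± 0.08, adjusted p = 0.052), and the 2 members that rose were CRELD2 (0.45 ± 0.09) and the ER chaperone HSPA5 (0.27 ± 0.08). HSPA5 lost its call in 15 of 23 alternatives. The list's median log2 fold change was -0.46; it was -0.45 with slide as a block, -0.51 on slide 1 alone and -0.48 between the IGF-I arrays without and with TNF high on slide 2. Camera's adjusted p was 6.27e-11, and with an estimated correlation the adjusted p was 0.236. Of 32 placental nutrient transporters 8 rose and 7 fell (10 and 8 over the list alone), and camera's adjusted p was 0.973. SLC7A11, the leucine transporter SLC43A1 (-1.70 ± 0.22) and the cationic amino acid transporter SLC7A1 (-0.72 ± 0.08) fell. The amino acid transporters SLC7A8 (0.70 ± 0.18) and SLC43A2 (0.59 ± 0.12), the taurine transporter SLC6A6 (0.36 ± 0.08), the fatty acid transporter SLC27A4 (0.75 ± 0.09) and the transferrin receptor TFRC (0.59 ± 0.10) rose.

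**Figure D2:**
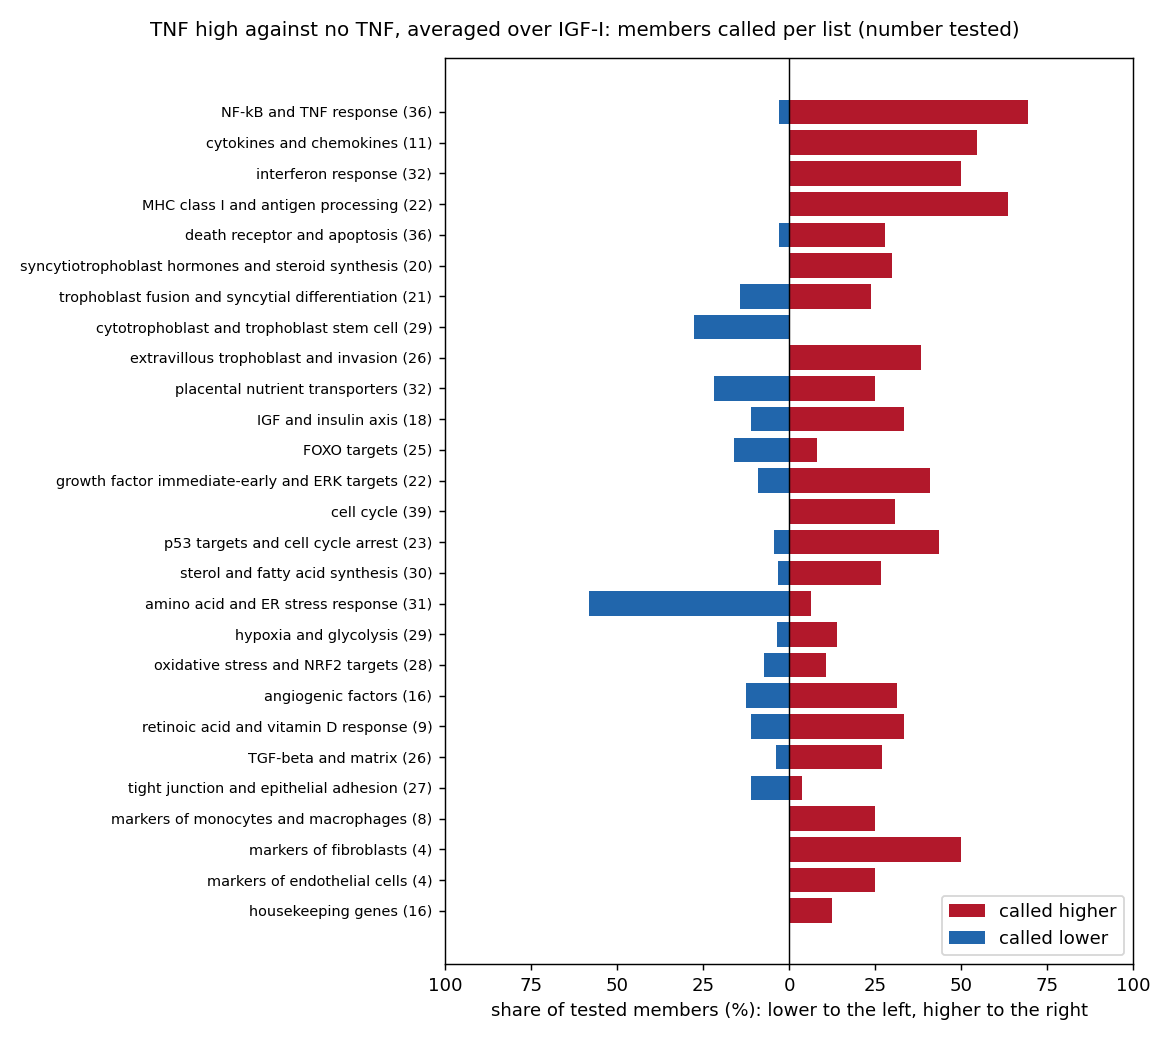
Share of each fixed list's tested members (horizontal axis, %) that limma called higher (red, to the right) or lower (blue, to the left) with TNF high, averaged over IGF-I; the number tested stands in brackets. In the NF-kB list 25 of 36 were higher, and in the amino acid and ER stress list 18 of 31 were lower.

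Metabolic and signalling lists were mixed. Of 30 sterol and fatty acid synthesis genes 8 rose and 1 fell (17 and 2 adjusted over the list alone). HMGCS1 (0.80 ± 0.09 SE) and HMGCR (0.45 ± 0.09), both of the mevalonate pathway, rose and SREBF1 (-0.46 ± 0.08) fell. Of 9 retinoic acid and vitamin D response genes 3 rose and 1 fell (6 and 1 over the list alone), with CYP26A1 and PLAAT4 (2.05 ± 0.10) highest. Of 26 TGF-beta and matrix genes 7 rose and 1, the intermediate filament VIM (-0.62 ± 0.10), fell (the same over the list alone). For these 3 lists the camera adjusted p was 3.64e-05, 0.0042 and 0.048, and with an estimated correlation the adjusted p was 0.280, 0.244 and 0.466. The TGF-beta and matrix call was lost in 14 of 23 alternatives. Of 18 genes of the IGF and insulin axis 6 rose and 2 fell (7 and 4 over the list alone), with STC2 at -0.93 ± 0.08, PHLDA2 at 0.76 ± 0.15 and IGF2 at 0.59 ± 0.16. IGF2 lost its call in 13 of 23 alternatives. The receptors IGF1R (0.26 ± 0.09) and INSR (-0.22 ± 0.07) and the adaptor IRS2 (-0.26 ± 0.09) did not pass, and IRS1, IGFBP1 and IGFBP3 were not well above background on both arrays of any group. Of 22 immediate-early and ERK target genes 9 rose and 2 fell (10 and 4 over the list alone), the latter being MYC (-1.54 ± 0.09) and EGR1 (-0.86 ± 0.23).

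Counts of genes that rose and fell were 2 and 4 of 25 FOXO targets, 4 and 1 of 29 hypoxia and glycolysis genes, 3 and 2 of 28 oxidative stress genes, 5 and 2 of 16 angiogenic factors and 1 and 3 of 27 tight junction genes. Adjusted over the list alone they were 3 and 6, 9 and 2, 3 and 2, 6 and 3, and 1 and 4. VEGFA, the vascular growth factor, fell (-0.80 ± 0.12 SE) and ANGPT2 rose (1.05 ± 0.23). Over the alternatives ANGPT2 ranged from 0.14 to 1.24, and 6 of 22 ended its call. For these 5 lists the camera adjusted p was 0.385, 0.104, 0.696, 0.175 and 0.781, for the IGF axis 0.336 and for the immediate-early genes 0.089. Of markers of cells that the line should not hold, 2 of 8 monocyte markers rose (LAPTM5 at 1.98 ± 0.27 and ITGAM at 1.06 ± 0.11) while CD14 (0.06 ± 0.13) did not pass. LAPTM5 ranged from 0.29 to 2.27 over the alternatives. Of 4 fibroblast markers 2 rose (ACTA2, 1.43 ± 0.12, and COL1A1, 0.38 ± 0.08), and 1 of 4 endothelial markers did (CDH5, 0.31 ± 0.09). CDH5 lost its call in 17 of 23 alternatives. Counts over these lists alone were the same, and camera's adjusted p was 0.064, 0.125 and 0.858. Of 16 housekeeping genes 2 rose (TFRC and B2M, 0.50 ± 0.09) and 0 fell, 3 and 0 over the list alone, with a median log2 fold change of 0.14 (camera adjusted p = 0.043, lost in 13 of 23 alternatives, and adjusted p = 0.465 with an estimated correlation). The median over all genes was 0.01.

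TNF high moved many genes in the same direction with and without IGF-I. Without IGF-I, LFNG rose from -1.79 ± 0.12 to 2.88 ± 0.11 (SD, n = 2 each), and RELB rose by 2.71 ± 0.11 (SE). With IGF-I, LFNG rose from -2.05 ± 0.24 to 2.68 ± 0.11, and RELB rose by 2.62 ± 0.11. CTSE, C3 and IL32 were also among the 6 smallest p-values of both comparisons, joined by IGFL1 without IGF-I (at least 2.68-fold) and SAA2 with it (6.16-fold). Without IGF-I 875 genes were called, 439 higher and 436 lower, and with it 1255, 578 higher and 677 lower. These comparisons share no array. Across all 22157 genes their log2 fold changes correlated with Pearson r = 0.653 and Spearman rho = 0.597 (genes are not independent replicates). Of the 875 genes, 865 had the same sign with IGF-I, and 588 were called in both in the same direction, against 24.8 for independent lists. NF-kB members higher were 21 of 36 in both comparisons, and amino acid and ER stress members lower were 14 of 31 without and 15 of 31 with IGF-I.

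The count without IGF-I was 546 with slide as a block and 9 on slide 1 alone, and it fell to 346 without control replicate 1, to 249 and 213 without TNF-high replicates 1 and 2, and to 531 without either IGF-I array. The count with IGF-I was 942 with the block and 1 on slide 1 alone. It fell to 153 and 227 without IGF-I replicates 1 and 2, 386 and 652 without IGF-I plus TNF-high replicates 1 and 2, 765 without either TNF-high array and 792 without either IGF-I plus TNF-low array. The 2 IGF-I arrays are its control group.

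Whether IGF-I changed the response to TNF high was tested as an interaction. CHAC1 had the smallest p: its fold change with TNF high was higher by 2.15 ± 0.27 (SE) on the log2 scale with IGF-I, and this did not pass (adjusted p = 0.563). It gained a call in 3 of 23 alternatives, over which the value ranged from 1.73 to 2.44. Limma called 0 of 22157 genes, with 612 at an unadjusted p under 0.05 where chance gives 1108. Leaving out control replicate 2 gave 12 calls and leaving out IGF-I plus TNF-high replicate 1 gave 7. Without control replicate 2 or TNF-low replicate 2, an array of larger spot-to-spot spread is alone in its group. The interaction of TNF low with IGF-I also had 0 calls in limma, with 950 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.690. It had 200 calls without TNF-low replicate 2, 46 without control replicate 2 and 1 without TNF-low replicate 1 or IGF-I replicate 2.

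TNF at 100 pg/ml gave no call. Averaged over IGF-I (4 arrays against 4), TNFAIP3 had a log2 fold change of -0.02 (95% interval -0.22 to 0.19), NFKBIA -0.02 (-0.25 to 0.21), ICAM1 0.07 (-0.10 to 0.24), LFNG -0.01 (-0.25 to 0.23) and CGA -0.00 (-0.18 to 0.17). The dimmer BIRC3 had a wider interval (-0.84 to 0.17). The median over the 36 NF-kB genes was -0.02, and that over the 31 amino acid and ER stress genes was -0.04. Limma called 0 of 22157 genes, with 516 at an unadjusted p under 0.05 where chance gives 1108, and camera called 0 of 27 lists (smallest adjusted p = 0.827). A count below that of chance, here and for the interactions, is not evidence of no effect. Power was simulated for TNF high with as many arrays (0% recovered at 0.5 with 200 changed genes), and not for TNF low. The genes with the smallest p, which did not pass, included ANKRD20A1 (-0.55 ± 0.10 SE) and ACE2, which was well above background on 0 of 4 TNF-low and 2 of 4 untreated arrays and is given no fold change.

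The count for TNF low without IGF-I was 0 in limma, with 1465 genes at an unadjusted p under 0.05, and with IGF-I 0, with 293. The log2 fold changes of these 2 comparisons, which share no array, correlated with r = -0.093 (Spearman rho = -0.159). The smallest p without IGF-I was that of ACE2, not well above background on the TNF-low arrays (at least 1.30-fold lower, adjusted p = 0.212). That with IGF-I was SLC25A5-AS1 (adjusted p = 0.9999), with a log2 fold change between -0.99 and -0.37 over the alternatives. With slide as a block, or on slide 1 alone, the 3 counts stayed at 0. The average count became 213 without TNF-low replicate 2, 37 without control replicate 2 and 1 without TNF-low replicate 1, and the count without IGF-I became 415, 154 and 1. The first 2 of these left the array with the larger spot-to-spot spread as the lone sample of its group.

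**Figure D3:**
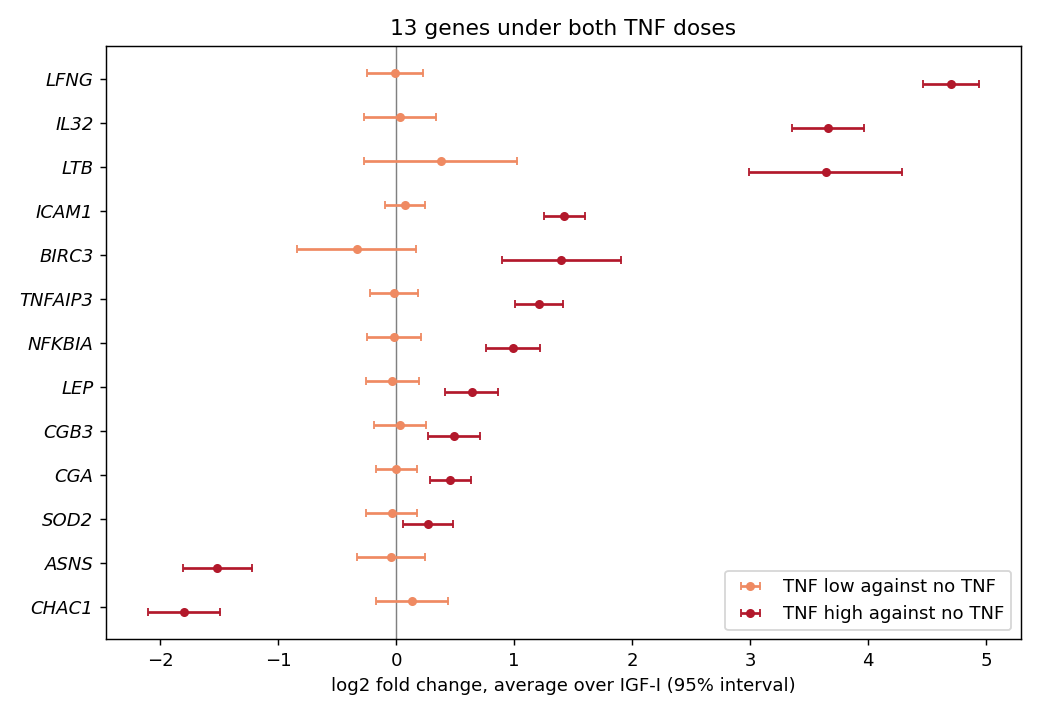
Log2 fold change against no TNF (horizontal axis), averaged over IGF-I, of 13 genes (vertical axis) at both TNF doses; points are limma estimates from 4 arrays against 4 and bars are 95% intervals. All 13 intervals for TNF low include 0, and for TNF high NFKBIA runs from 0.76 to 1.22 and CHAC1 from -2.11 to -1.50.

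Set directly against each other, the doses differed at 3823 genes, 2340 higher and 1483 lower with TNF high (4 arrays against 4). The 6 smallest p-values belonged to LFNG (4.71 ± 0.10 SE), CTSE (3.28 ± 0.08), RELB (2.68 ± 0.07), C3 (3.39 ± 0.10), IL32 (3.63 ± 0.14) and PSMB9 (2.17 ± 0.08). Of 36 NF-kB genes 27 were higher and 1 lower with the high dose (31 and 1 adjusted over the list alone). Of 31 amino acid and ER stress genes 4 were higher and 18 lower (4 and 20 over the list alone). Camera's adjusted p was 1.16e-19 and 9.17e-11, and with an estimated correlation the adjusted p was 0.177 and 0.260. The excess of higher genes depended on the setting: without TNF-low replicate 1 there were 1597 higher and 1675 lower, on slide 1 alone 59 and 69, and with quantile normalization 1940 and 1730. The gene count was 3164 with slide as a block and 128 on slide 1 alone. It was 2201 and 1939 without TNF-high replicates 1 and 2, 2208 and 2117 without IGF-I plus TNF-low replicates 1 and 2, and 2049 without IGF-I plus TNF-high replicate 1.

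IGF-I, averaged over the TNF levels (6 arrays against 6), raised a short list of genes. They included the lysosomal membrane protein LAMP3 (3.39-fold, log2 fold change 1.76 ± 0.19 SE), DRD5 (1.72 ± 0.20), the collagen receptor DDR2 (1.67 ± 0.15), LYPD4 (1.57 ± 0.19) and KLHDC7B (1.51 ± 0.12). Others were the channel gene BEST1 (at least 1.06-fold), the neuronal filament PRPH (1.19 ± 0.14), NIBAN1 (adjusted p = 0.042), antithrombin SERPINC1 (0.83 ± 0.11), DDIT4, an inhibitor of mTOR signalling (0.81 ± 0.10), cystatin CSTA (0.76 ± 0.10) and the NKG2D ligand ULBP1 (0.61 ± 0.08). The inducible nitric oxide synthase NOS2 fell (-0.84 ± 0.11). BEST1 was well above background on 4 of 6 arrays with IGF-I and on 0 of 6 without, DDR2 on 4 and 1. Over the alternatives DDR2 ranged from 0.26 to 1.81, and 11 of 21 ended its call. Limma called 22 genes, 21 higher and 1 lower, with adjusted p between 0.013 and 0.043.

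These IGF-I calls depended on the fit. Fits without control replicate 2 or TNF-low replicate 2 leave an array of larger spot-to-spot spread as the lone sample of its group. With slide as a block 0 of the 22 were called (smallest adjusted p = 0.054, all 22 at an unadjusted p under 0.05). Among the called genes LAMP3 then had 1.70 ± 0.21, and KLHDC7B 1.46 ± 0.13. On slide 1 alone LAMP3 had 1.56 and KLHDC7B 1.44, with 0 calls, and between the TNF-high arrays without and with IGF-I on slide 2 they had 0.80 and 0.62. Leaving out 1 array gave 0 calls for 6 arrays (control replicate 1, both TNF-high arrays, both IGF-I arrays and IGF-I plus TNF-low replicate 2). It gave 5 without IGF-I plus TNF-high replicate 2, 7 without IGF-I plus TNF-low replicate 1 and 14 without TNF-low replicate 1. It gave 34 without control replicate 2, 78 without IGF-I plus TNF-high replicate 1 and 536 without TNF-low replicate 2. Without both arrays of larger spot-to-spot spread KLHDC7B alone was called.

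The amino acid and ER stress response was the list that IGF-I raised. Of 31 tested members 2 rose and 0 fell, CHAC1 (0.85 ± 0.11 SE) and DDIT4, and adjusted over the list alone 16 rose. Among those not called over all genes were TRIB3 (0.68 ± 0.12), DDIT3 (0.58 ± 0.09), ASNS (0.57 ± 0.10) and PSPH (0.45 ± 0.07). For CHAC1 the estimated effect of IGF-I was larger at TNF high than without TNF, by 1.73 to 2.44 over the alternatives. Its 0.85 is thus an average of unequal estimates, though this interaction did not pass in the main fit. The list's median log2 fold change was 0.21; it was 0.20 with slide as a block, 0.19 on slide 1 alone and 0.41 between the TNF-high arrays without and with IGF-I on slide 2. Camera's adjusted p was 4.87e-13, and with an estimated correlation the adjusted p was 0.537. Camera also called the cell cycle list (median -0.02, adjusted p = 0.018), the 4 endothelial markers (median -0.12, adjusted p = 0.020) and the syncytiotrophoblast hormones (median -0.05, adjusted p = 0.042) lower than other genes, with 0 members called. For these the adjusted p was 0.958, 0.537 and 0.958 with an estimated correlation, and the calls were lost in 7, 8 and 11 of 22 alternatives. Of the other 23 lists, 0 were called. The NF-kB median was 0.08, and IGF1R (-0.09 ± 0.07), INSR (0.09 ± 0.06), IRS2 (-0.04 ± 0.08), CGA (-0.07 ± 0.06) and GCM1 (-0.27 ± 0.08) did not pass.

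**Figure D4:**
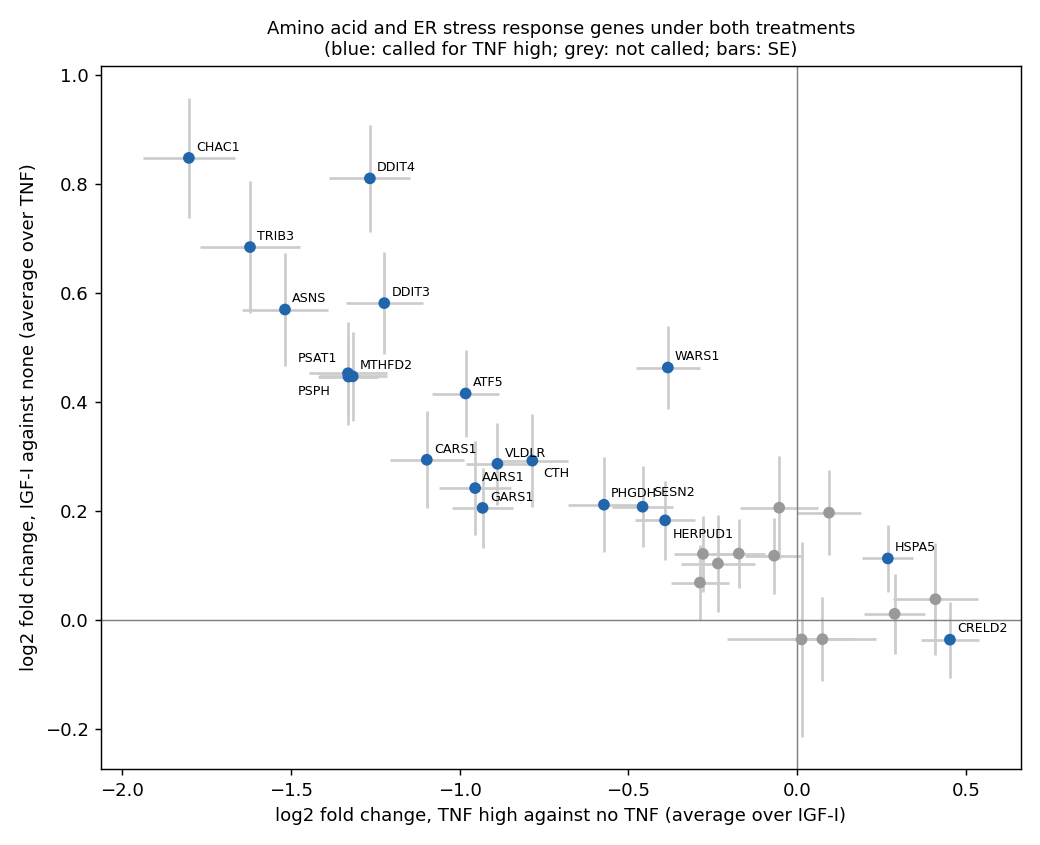
Log2 fold change of the 31 tested amino acid and ER stress response genes with TNF high (horizontal axis, average over IGF-I) and with IGF-I (vertical axis, average over TNF); blue points were called for TNF high and grey ones were not, and bars are standard errors. CHAC1 lies at -1.80 and 0.85 and ASNS at -1.52 and 0.57.

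IGF-I alone, without TNF, gave no call (2 arrays against 2). A fit without control replicate 2 leaves control replicate 1, of larger spot-to-spot spread, as the only control array. The smallest p-values were those of KLHDC7B (-0.33 ± 0.02 without and 1.68 ± 0.00 with IGF-I, SD, n = 2 each) and ACE2 (at least 1.61-fold lower), with an adjusted p of 0.101. Limma called 0 of 22157 genes, with 1597 at an unadjusted p under 0.05. It called 185 without control replicate 2, and 1 without either TNF-low array or without IGF-I replicate 1. With slide as a block or on slide 1 alone the count was 0.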

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

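The alternatives without both arrays of larger spot-to-spot spread and with slide 1 alone, used for the ranges below, were chosen after the results were seen. There were 2 lists that stood out because their response to TNF high differed between the IGF-I levels in the interaction test. The 39 cell cycle genes had a median interaction of 0.092 (log2), higher with IGF-I (camera adjusted p = 0.020), with an adjusted p of 0.978 with an estimated correlation and 0.958 in fry. The 30 sterol and fatty acid synthesis genes had a median of 0.11 (camera adjusted p = 0.036), with an adjusted p of 0.978 with an estimated correlation and 0.958 in fry. Limma called 0 genes of either list, and 0 of all 22157 genes, for this interaction, with 612 at an unadjusted p under 0.05.

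Both shifts were small and depended on the alternative. Over the alternatives the cell cycle median ranged from -0.01 to 0.20, and 5 of 23 ended its call. The sterol median ranged from 0.04 to 0.20, and 13 of 23 ended its call. No biological explanation was tested for either list. Groups of 2 arrays are too small to test a single array as an outlier.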

How the results depend on the processing

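Slide 1 alone and leaving out both arrays of larger spot-to-spot spread were chosen after the results were seen. No called value of a named gene changed sign, but the balance of higher and lower genes did change. Between the doses it went from 2340 and 1483 to 1597 and 1675 without TNF-low replicate 1, to 1818 and 1862 without both arrays of larger spread, and to 59 and 69 on slide 1 alone. For TNF high on average it went from 1730 and 1596 to 423 and 521 without a filter on dim probes, 1189 and 1379 without control replicate 1, 980 and 1040 or 840 and 918 without TNF-high replicate 1 or 2, 817 and 877 without IGF-I replicate 1, 967 and 1033 without IGF-I plus TNF-high replicate 1, 1648 and 1802 without both arrays of larger spread, and 53 and 81 on slide 1 alone. The balance within each IGF-I level also changed under some alternatives. Below are the total counts that moved by more than 1.5 times or crossed 0. Except where stated, the cause was not tested.

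With normexp background the calls for IGF-I averaged over TNF rose from 22 to 76, those for IGF-I without TNF from 0 to 11 and those for the interaction of TNF high and IGF-I from 0 to 1. Quantile normalization gave 1 call for TNF low without IGF-I and 1 for IGF-I without TNF. Without a filter on dim probes there were 944 calls for TNF high on average, 0 for IGF-I on average, 161 for TNF high without and 144 with IGF-I, and 1028 between the doses. With the filter on all 12 arrays there were 48 for IGF-I on average and 3 for IGF-I without TNF. With slide as a block there were 0 for IGF-I on average and 546 for TNF high without IGF-I. With a trended robust variance there were 107 for IGF-I on average, 1485 for TNF high without IGF-I, 5 for IGF-I without TNF and 1 for the interaction of TNF high and IGF-I. With only the groups compared, which leaves fewer samples, there were 102 for TNF high without and 432 with IGF-I.

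With the replicate number as a block, which treats the replicates as pairs, there were 51 calls for IGF-I on average and 7 for IGF-I without TNF. The pairing check (4 of 15 pairs of groups above 0.1, median 0.058) did not pair the samples.

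Without both arrays of larger spot-to-spot spread there was 1 call for IGF-I on average, 538 for TNF high without IGF-I and 2 for TNF low without IGF-I. On slide 1 alone, with fewer samples, there were 134 for TNF high on average, 0 for IGF-I on average, 9 for TNF high without and 1 with IGF-I, and 128 between the doses.

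Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, the calls ranged from 1694 to 3902 for TNF high on average, 0 to 213 for TNF low on average, 0 to 536 for IGF-I on average, 213 to 1176 for TNF high without and 153 to 1566 with IGF-I, 0 to 415 for TNF low without and 0 to 0 with IGF-I, 0 to 185 for IGF-I without TNF, 0 to 12 for the interaction of TNF high and IGF-I, 0 to 200 for that of TNF low and IGF-I, and 1939 to 4468 between the doses. The report names the arrays. Without control replicate 2 or TNF-low replicate 2, the lone array of the group was the one of larger spot-to-spot spread.

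For the named genes, 216 of 273 called results lost their call under at least 1 of the 21 to 23 alternatives run for each, and 57 under 0. Slide 1 alone, with fewer samples, ended all 216 of these. Without a filter on dim probes 141 were lost, the most under any other alternative. List medians stayed on their side of the threshold in 2356 comparisons with an alternative, lost a call in 71 and gained 1 in 26. A block by scan date equals that by slide and was not run separately, and only the groups compared was not run for IGF-I on average, which uses all 12 arrays. Signal over background limits the dim genes: 18515 of the 22157 genes were well above background on all 12 arrays. The sizes of dim genes varied with the alternative too. With TNF high on average SLC43A1 ranged from -2.12 to -0.51 and EGR1 from -1.18 to -0.24, and 13 of 22 alternatives ended the call of EGR1.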

Other observations

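The splits of the IGF-I arrays within TNF levels, the opposite-direction correlations with arrays left out, slide 1 alone and leaving out both arrays of larger spot-to-spot spread were chosen after the first results were seen. Genes that TNF high lowered tended to be higher with IGF-I. Of the 22 genes called for IGF-I, 18 were called lower with TNF high, among them LAMP3, KLHDC7B, DRD5 and LYPD4, and 2 higher, 1 of them NOS2. The hypothesis that TNF high and IGF-I act in opposite directions was tested on fold changes that share no array, TNF high against control and IGF-I plus TNF low against TNF low, with the amino acid list left out. Over 3306 genes called for TNF high these correlated with r = -0.417 (-0.478 with the TNF effect measured with IGF-I), and over all 22157 tested genes with r = -0.164 (-0.167). Among the lowered genes alone r was -0.317 (-0.478), and among the raised genes alone 0.087 (-0.008). A shift between the slides would make this correlation positive, and on slide 1 alone it was -0.390. A fault of TNF-low replicate 1, which stood apart from the other arrays, would end it, but without that array it was -0.388, and without both arrays of larger spot-to-spot spread -0.405. Of the 1578 lower genes, 1357 (86.0%) were higher with IGF-I, against 808 of 1728 higher genes (46.8%) and 14497 of all 22157 (65.4%). Without TNF-low replicate 1 these shares were 73.0%, 32.9% and 46.7%. The median change with IGF-I was 0.21 in the lowered, -0.01 in the raised and 0.07 in all genes. IGF-I may thus oppose part of what TNF high lowers, as a hypothesis found and tested on the same data. Cell density and the state of the medium were not measured and stay open.

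The fall of the amino acid and ER stress genes with TNF high was weighed against technical explanations. A difference in scaling between arrays would move genes of the same signal alike, but the list's median lay -0.483 (spread 0.146) from that of genes matched on signal. The spread given here and below is an approximate standard error of the list's median. It treats the genes of the list as independent, which they need not be, and is not their SD. A difference between slides, or the arrays of larger spot-to-spot spread, would end the shift on slide 1 alone or without those arrays, but its median was -0.511 (spread 0.160) and -0.451 (spread 0.147). The rise of the same list with IGF-I had a median of 0.191 (spread 0.051) on slide 1 alone and 0.216 (spread 0.054) without those arrays. These values argue against each explanation as the whole cause of the fall with TNF high. For the rise with IGF-I they argue against the slides and those arrays as the whole cause, and scaling was not tested. No biological explanation was tested. Cell number and nutrients left after 48 h were not measured and stay open.

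The genes called for IGF-I were weighed in the same way. With slide as a block their fold changes had a median ratio of 0.964 (SD 0.049) to those without it. Without both arrays of larger spot-to-spot spread the ratio was 0.919 (SD 0.080). A gene was called only if its spread within groups was small, and a large shift from the slide or those arrays would widen that spread. High ratios were thus favoured by the choice of genes and cannot exclude either explanation. The calls ended, all 22 with the block and 21 without those arrays. With the block the standard errors were 1.10 times as large, and the adjusted p began at 0.054.

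Other splits of the same arrays, in a fit with the split alone, were counted. For TNF high averaged over IGF-I 1 of 35 splits, the real one, called as many genes (3550, the highest other 0), and between the doses 1 of 35 (3469, the highest other 0). Every other split put TNF-high arrays on both sides, which widened its spread, so the size of these gaps was largely built in. The rank of 1 of 35 is the lowest that 35 splits allow. It speaks against chance for both only if the 2 arrays of a group are separate samples, which the labels do not say. For TNF low, and for IGF-I with the split alone in the fit, the real split called 0 genes, so all 35 of 35 and 100 of 100 splits reach it by construction and the counts say nothing about chance. The highest other for TNF low, 15, was the split by IGF-I. The highest other for IGF-I, 2329, put all 4 TNF-high arrays on 1 side, which points to the structure that TNF gives the samples. Within TNF levels, with the level in the fit, 1 of 100 splits drawn from 108 called as many as the real 2 genes, and the highest other called 1. A margin of 1 gene is too small to exclude chance here, and with slide as a block 0 of the IGF-I calls passed.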
